A study of Mus musculus with 8 samples.

How the data were processed

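In total, 8 liver RNA samples of male mice of the C57BL/6J strain, as labelled, were measured on Affymetrix GeneChip whole-transcript arrays, 4 from wild type mice and 4 from mice that carry the E167K coding variant of Tm6sf2 as a knock-in. Group and replicate number came from the labels of each array. The labels contradict each other on diet: the description of the whole series gives a high-fat diet for 20 weeks, and the treatment note of each array gives either a sucrose-rich diet without fat or chow for 14 weeks. The diet of these 8 arrays is therefore not settled, and no result below is tied to one. Per the labels' protocols, wild type animals were littermates, and biotin-labelled cDNA was made from 400 ng of total RNA. The labels do not say outright that each array holds a separate animal, so p-values measure the spread between these samples.

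The deposited table holds log2 expression values, 1 per probe set and array, which the authors had normalized across arrays; the submitters' processing notes name RMA (background correction, quantile normalization and probe summary) and limma, without versions. The log2 scale and the normalization were checked on the values: they run from 0.32 to 13.66, with array medians of 3.73 to 3.80. The array's annotation version and genome build are not given in the sources used here. RMA makes the arrays' distributions nearly equal, so a shift of most genes in one group would be removed from these values, and it compresses changes of dim probe sets and of those near the top of the scale. Detection calls per probe set were not used here. There is no read depth for arrays, and the number of arrays limits the precision.

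Of 41345 probe sets, the platform annotation lists 23521 with exactly 1 gene symbol, 1814 with several, and does not list 16010 with a gene. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6: 23328 matched, 193 did not and kept their listed symbol, and 0 symbols changed. That table also served for which genes neighbour each other, and no coordinates were taken from it. Of the 22180 genes, 1082 had more than 1 probe set, and the probe set with the highest mean over the 8 arrays was kept. A gene was tested if at least 4 of the 8 arrays, whatever their group, lay above the dim limit. That limit is the 40th percentile of the array's values over the probe sets with exactly 1 gene symbol. This left 13449 genes and set aside 8731 dim ones.

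Knock-in was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, genotype as the only term, two-sided, Benjamini-Hochberg adjustment over all tested genes, threshold 0.05). All changes are log2 knock-in minus wild type, with the standard error (SE) from the model, and group values are means ± SD of 4 arrays. A second count, of genes with unadjusted p under 0.05 and a change of at least 1.5-fold, describes the data without error control. Tm6sf2 also had an exact two-sided permutation test, for which the smallest p that 4 against 4 arrays allow is 0.0286.

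There were 37 fixed lists: 24 gene lists (fatty acid and triglyceride synthesis, cholesterol synthesis, PPARα targets with fatty acid oxidation, VLDL assembly, lipid droplets, gluconeogenesis with glycogen, insulin signalling, unfolded protein response, bile acids with sterol transport, inflammatory cytokines, acute phase, extracellular matrix, interferon-stimulated, NRF2 targets, xenobiotic metabolism, male-biased, female-biased, clock, cell cycle, respiratory chain, lysosome, neighbours of Tm6sf2, pericentral and periportal genes) and 13 marker lists of cell types. The 33 lists with at least 5 tested members were tested by limma's camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over those lists. Camera asks whether the members move more in one direction than other genes. It was also run with the correlation estimated for each list and on ranks. Limma's fry was run for a shared direction and for change in either direction. Fry asks whether members change at all, not whether they change more than other genes, so a pass does not set a list apart. Members of a list were also adjusted over the list alone, which does not control error across the lists.

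Named genes followed a rule: Tm6sf2, then up to 12 genes per direction past the threshold with the largest change, with open places filled by the smallest unadjusted p and given as values, and the leading members of each list. Predicted genes took no place under the rule, which leaves open whether members of lists that did not pass are named; those with unadjusted p of 0.05 or more were left out after values were seen, which also sets the number of groups examined for stray arrays. Samples, comparison, test, filter, lists, naming rule and the alternatives were chosen before the data were examined, except for the clock score as a covariate. Chosen after values were seen were the 2 called genes outside the rule (Gm3893 and B930025P03Rik), Apob and Mttp, further list members named because they passed adjusted over the list alone or had a low unadjusted p, and the lists and tests that the closing parts mark as such.

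The alternatives were the replicate number as a block, no filter and a stricter filter at the 60th percentile, a further quantile normalization, centring on array medians, a trended and robust variance prior, array weights, the mean of a gene's probe sets, every probe set as its own item, the other set tests, and leaving out each array in turn. The fit was tested on simulated data with the real arrays' spread over 13449 genes, 200 of them changed, in 10 simulations. It recovered 36% of genes changed by 0.5 on the log2 scale, 78.2% of those changed by 1 and 96.9% of those changed by 2, and 5.77% of its calls were false. The adjusted threshold depends on how many genes change and by how much. These rates therefore hold for the simulated 200 genes and may be too high for the real comparison. A list shifted by 0.5 was called in 10 of the 10 simulations and 0 unshifted lists were called, with genes simulated as independent.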

Results

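To ask how the E167K variant of Tm6sf2, a membrane protein of the endoplasmic reticulum that takes part in the lipid loading of very low density lipoprotein (VLDL), acts on glucose and lipid metabolism, liver expression was compared between 4 wild type and 4 knock-in samples from male mice on whole-transcript arrays. The labels disagree on whether these mice ate a high-fat diet for 20 weeks or a sucrose-rich or chow diet for 14 weeks. The arrays had similar distributions, and log2 values had medians of 3.73 to 3.80 per array. Across all 41345 probe sets, any 2 arrays correlated at 0.973 to 0.980. The first principal component held 24.4% of the variance of the 13449 tested genes and separated the genotypes, with wild type arrays at -21.8 to -6.10 and knock-in arrays at 5.01 to 20.0. Across all probe sets, the median correlation was 0.977 within groups and 0.976 between them.

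Tm6sf2 itself was well expressed in both groups, at 9.72 ± 0.22 in wild type and 9.66 ± 0.27 in knock-in liver (log2, mean ± SD, n = 4 each, exact permutation p = 0.686). The change was -0.06 (SE 0.16, 95% interval -0.42 to 0.29, limma adjusted p = 0.928), and its sign turned to 0.0037 without wild type replicate 3 and to 0.06 without knock-in replicate 1. Since the variant is a coding change, the level of the transcript does not check the genotype labels.

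Knock-in livers had 9 genes past the threshold, 3 higher and 6 lower. Nnt, the mitochondrial transhydrogenase that makes NADPH, rose by 1.05 (SE 0.09, adjusted p = 0.00951). Kcnk5, a potassium channel, rose by 1.30 (SE 0.16, adjusted p = 0.0439), and Cyp2g1, a cytochrome P450, rose by 1.55 (SE 0.20, adjusted p = 0.0494). Irs2, the docking protein that carries the signal of the insulin receptor in the liver, fell by 0.75 (SE 0.10), from 8.89 ± 0.13 to 8.14 ± 0.12 (n = 4, limma adjusted p = 0.0494). Ide, the insulin-degrading enzyme, fell by 0.94 (SE 0.10, adjusted p = 0.0226). Hspa1a, a stress-inducible heat shock protein, fell by 0.81 (SE 0.10, adjusted p = 0.0439), and Il17rb, an interleukin receptor, fell by 0.62 (SE 0.08, adjusted p = 0.0494). The remaining 2 were transcripts of predicted genes: Gm3893 fell by 4.27 (SE 0.22, adjusted p = 0.000136), from 8.03 ± 0.10 to 3.76 ± 0.49, close to the dim limit, and the non-coding B930025P03Rik fell by 1.13 (SE 0.13, adjusted p = 0.0378). In GRCm38.p6, B930025P03Rik lies near Irs2, with 4 annotated genes between them, on the chromosome that also holds Tm6sf2. The probe sets were 17296489 for Nnt, 17303722 for Kcnk5, 17475458 for Cyp2g1, 17507374 for Irs2, 17364251 for Ide, 17344132 for Hspa1a, 17304338 for Il17rb, 17413075 for Gm3893 and 17507361 for B930025P03Rik. In each of the 9 genes, the 4 knock-in arrays lay apart from the 4 wild type arrays.

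Gm3893 belongs to a family of near-identical copies, so which copy was measured is uncertain; all 3 of its probe sets were lower. In 2 of the 4 knock-in arrays its value lay below the dim limit, so the size of its fall is uncertain. Hspa1a and Hspa1b, and the genes of the Cyp2a family, are close copies too, so the values of each copy are uncertain. Nnt is known to differ between substrains of C57BL/6 mice. Ide, Wdfy1 and Nlrp12 were also listed for such differences, after their values had been seen. The brightest probe set of another listed gene, Entpd4 with its copy Entpd4b, was at -0.58 in the knock-in (SE 0.10, limma adjusted p = 0.0954 over all probe sets).

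The genes that filled the open places of the naming rule lay just short of the threshold, with adjusted p up to 0.0588, and are given as values. Abcg8, part of the transporter that exports sterols into bile, was higher by 0.88 (SE 0.12), Cyp2a5 by 2.09 (SE 0.29), the sulfotransferase Sult5a1 by 1.40 (SE 0.21), Wdfy1 by 1.22 (SE 0.17) and Cyp3a59 by 0.97 (SE 0.14). Lncbate1, the ribonucleotide reductase subunit Rrm2 and Fn3k were higher by 0.67 to 0.94. On the other side, Hspa1b was at -1.89 (SE 0.29), the cytokine Il1b at -1.70 (SE 0.25), the imprinted gene Peg3 at -0.99 (SE 0.14) and the inflammasome-related Nlrp12 at -0.75 (SE 0.11). Adgrg2, Mcc and Fam205a2 were at -0.96 to -0.71, and Speer4c was lower in the knock-in, where all 4 arrays lay below the dim limit, so its size is not given. Cep72 was higher in the knock-in, and its size is not given because all 4 wild type arrays lay below the limit. Abcg8 and Peg3 passed under the stricter filter, a further quantile normalization, the trended prior, array weights and the mean of probe sets. They did not pass under the replicate block or with no filter, and Abcg8 passed in no leave-one-out fit. The threshold therefore marks no clear break between them and calls such as Cyp2g1.

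At adjusted p under 0.10 there were 47 genes, and 1519 had an unadjusted p under 0.05 against 672 by chance, 808 higher and 711 lower. Of these, 290 changed by at least 1.5-fold, 147 higher and 143 lower. In 963 genes (7.16%) the groups did not overlap, against 2.86% by chance. Of the 9 calls, 8 were lost on leaving out at least 1 array. The count of all genes past the threshold was 3 without wild type replicate 1, of which 2 were among the 9. It was 1 without wild type replicate 2 and 2 without wild type replicate 4. Without knock-in replicates 1, 2 and 3 it was 1, 4 and 1, and of the 4 genes, 3 were among the 9. Gm3893 passed under each of the 18 alternatives, Nnt under 13 and Ide under 10. Cyp2g1 passed under 4 of 17, since the stricter filter leaves it out, and the others under 6 to 8 of 18. The count ran from 1 with a clock score as a covariate to 73 with a trended and robust prior.

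**Figure D1:**
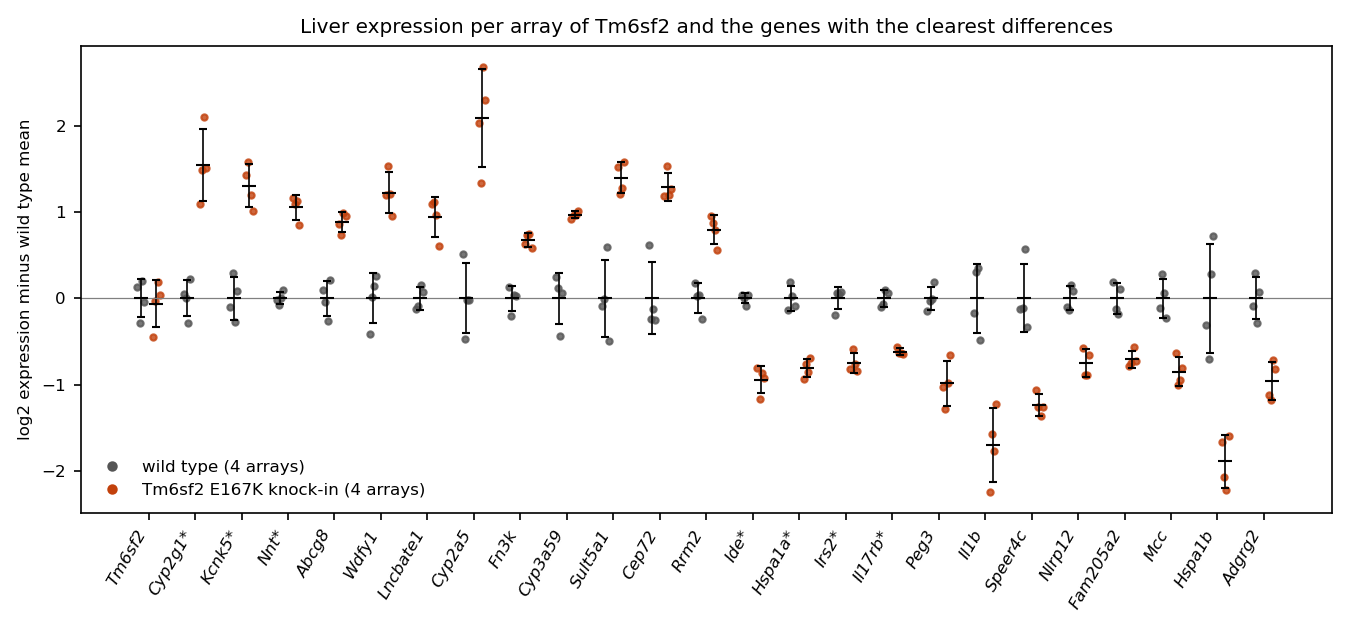
Log2 expression of each array minus the wild type mean of that gene, for Tm6sf2 and the genes named by the rule (grey, 4 wild type arrays; orange, 4 knock-in arrays; bars, mean and SD), with an asterisk on the 7 genes whose limma adjusted p was under 0.05. Tm6sf2 overlaps between groups, Nnt lies at 1.05 and Ide at -0.94 in the knock-in, Cep72 and Speer4c have a group below the dim limit, and the larger changes of Cyp2a5 and Il1b come with a wider spread.

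Among bile acid and sterol genes, the directions were opposite within the list. Abcg8 and Abcg5, the paired sterol exporters, were higher by 0.88 and 0.71 (SE 0.12 and 0.14), while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -0.84 (SE 0.24), Cyp8b1, which makes cholic acid, at -0.74 (SE 0.14), and Abcb4, the phospholipid exporter of bile, at -0.36 (SE 0.08). Of 15 members, 0 passed over all genes, and 2 higher and 3 lower passed adjusted over the list alone. The list had no shared direction (mean 0.00097, camera adjusted p = 0.900), while fry for change in either direction gave adjusted p = 3.76e-05.

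In fatty acid and triglyceride synthesis, 14 of 20 members were higher. Srebf1, the lipogenic transcription factor, was higher by 1.01 (SE 0.19), Lpin1 by 1.74 (SE 0.32) and Thrsp by 1.46 (SE 0.34), and these 3 passed adjusted over the list alone, while 0 passed over all genes. Elovl6, a fatty acid elongase, was at -0.54 (SE 0.21). The list had a mean of 0.29 and adjusted p = 0.0878. PPARα targets with fatty acid oxidation were lower as a list, 16 of 20 members with a mean of -0.22 and a median of -0.10 (adjusted p = 0.0174; adjusted p = 0.798 with an estimated correlation). The smallest p belonged to the peroxisomal enzyme Ehhadh, at -0.43 (SE 0.11), and the hormone Fgf21, at -1.06 (SE 0.27). The kinase Pdk4 was at -1.17 (SE 0.37) and the thioesterase Acot1 at -0.71 (SE 0.23). Ehhadh and Fgf21 passed adjusted over the list alone and 0 over all genes. The list lost its call without wild type replicate 3 (0.0723), wild type replicate 4 (0.171) or knock-in replicate 4 (0.109).

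VLDL assembly, where Tm6sf2 acts, was near 0 as a list: 9 of 17 members were higher and 8 lower, 0 passed either way, 0 had an unadjusted p under 0.05, and camera gave adjusted p = 0.978. Apob, the core protein of VLDL, was at -0.0037 (SE 0.07; 0.010 after a further quantile normalization) at 13.2, near the top of the scale, and Mttp, which loads it with lipid, was at -0.15 (SE 0.09, adjusted p = 0.587). In lipid droplets and storage, Fabp4 was higher by 0.62 (SE 0.14) and passed adjusted over the list alone, and Dgat2, which makes triglyceride, was higher by 0.36 (SE 0.10). The droplet proteins Cidea and Plin2 were at -1.48 (SE 0.49) and -0.39 (SE 0.14), each with an unadjusted p under 0.05, and Cidec was at -0.99 (SE 0.53). Over all genes 0 of 19 passed, and the list had a mean of -0.05 with adjusted p = 0.760. Cholesterol synthesis had 12 of 17 members higher, 0 past either test and 2 lower at unadjusted p under 0.05, Hmgcs1 and Hsd17b7 (adjusted p = 0.760).

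In glucose metabolism, Foxo1, the transcription factor that insulin inhibits, was higher by 0.56 (SE 0.11), the glycogen phosphorylase Pygl by 0.35 (SE 0.08), the glucokinase regulator Gckr by 0.34 (SE 0.11) and the coactivator Ppargc1a by 0.33 (SE 0.11). Igfbp1, a secreted insulin-responsive protein, was at -0.99 (SE 0.20). Over all genes 0 of 15 members passed, and these 5 passed adjusted over the list alone. The list had a mean of 0.06 and adjusted p = 0.0878, and by fry for change in either direction adjusted p = 7.21e-08. Pck1 and G6pc, the classical gluconeogenic enzymes, were at 0.04 (SE 0.07) and -0.14 (SE 0.11). Pck1 lay at 13.0 in both groups, near the top of the scale, where changes are compressed. In insulin signalling, Irs2 fell over all genes, and Irs2 and the receptor adaptor Grb14, at -0.32 (SE 0.08), passed adjusted over the list alone. The list of 17 had a mean of -0.10 and adjusted p = 0.199, and by fry for change in either direction adjusted p = 2.91e-06.

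Most clock genes lay in 2 opposed arms. Ciart was higher by 2.51 (SE 0.46), Per3 by 1.49 (SE 0.32), Bhlhe40 by 0.89 (SE 0.19), Tef by 0.84 (SE 0.16), Per1 by 0.53 (SE 0.17), Nr1d2 by 0.52 (SE 0.12) and Cry2 by 0.43 (SE 0.11), which are outputs or repressors of the clock. The activators Npas2, Arntl and Clock were at -1.32 (SE 0.39), -1.20 (SE 0.42) and -0.29 (SE 0.10). The repressor Nr1d1 lay against its arm, at -0.20 (SE 0.19, adjusted p = 0.753). Over all genes 0 of 16 passed, and these 7 higher and 3 lower members passed adjusted over the list alone. As a list the clock was higher (mean 0.33, adjusted p = 0.00724), with adjusted p = 0.424 with an estimated correlation and 0.116 on ranks. Hours of collection are not given in the sources used here, and the mean of outputs minus activators was -1.46 to 0.27 in wild type and -0.05 to 1.59 in knock-in arrays.

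Interferon-stimulated genes were lower as a list, 11 of 13 members with a mean of -0.45 (adjusted p = 1.99e-05, but adjusted p = 0.714 with an estimated correlation). Usp18 was at -0.76 (SE 0.21), Mx2 at -0.74 (SE 0.24), Rsad2 at -0.70 (SE 0.22), Isg15 at -0.52 (SE 0.16) and Stat2 at -0.47 (SE 0.13); these 5 passed adjusted over the list alone and 0 over all genes. Acute phase proteins were higher as a list, 17 of 19 with a mean of 0.40 and a median of 0.09 (adjusted p = 0.00269; adjusted p = 0.746 with an estimated correlation), and 0 members passed either test. Orm3, Saa2, Saa3, Orm2 and Lcn2 were at 1.01 to 1.79, and others such as Hp, Fgb, Hpx and Cp were at -0.02 to 0.06. The latter had group means of 12.3 to 13.3, toward the top of the scale, where changes can be compressed. Among inflammatory cytokines, Il1b passed adjusted over the list alone and 0 of 16 over all genes (mean -0.10, adjusted p = 0.569). Extracellular matrix genes were higher, 12 of 14 with a mean of 0.30 (adjusted p = 0.00951; adjusted p = 0.746 with an estimated correlation), including Col6a1 at 0.71 (SE 0.21). The list had 0 members past either test, and its call was lost without wild type replicate 3 (0.0528) or knock-in replicate 4 (0.157, with a mean of 0.16) and with a stricter filter (0.0730).

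Respiratory chain genes were higher by small amounts, 19 of 20 with a mean of 0.15 (adjusted p = 0.000184; adjusted p = 0.424 with an estimated correlation). Cox5a was at 0.36 (SE 0.08) and passed adjusted over the list alone, Sdhb was at 0.26 (SE 0.08), and 0 passed over all genes; the list's call was lost with the clock score as a covariate (0.0890). All 14 tested members of xenobiotic metabolism were higher, with a mean of 0.43 and a median of 0.16 (adjusted p = 0.00055; adjusted p = 0.424 with an estimated correlation), with Cyp2a5 past the list alone, Gstt3 at 0.82 (SE 0.24) and 0 past over all genes. Cell cycle genes were higher, 10 of 15 with a mean of 0.21 (adjusted p = 0.0320; adjusted p = 0.746 with an estimated correlation), with Rrm2 and Tk1, at 0.80 (SE 0.12) and 0.79 (SE 0.19), past the list alone and 0 over all genes. That call was lost on ranks (0.131), with the mean of probe sets (0.149), with the clock score as a covariate (0.830) and without wild type replicate 1 (0.104) or 2 (0.0554) or knock-in replicate 2 (0.478) or 3 (0.058). Without knock-in replicate 2 the list's mean was 0.10.

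These 8 lists, 6 higher and 2 lower, rest on the preset correlation. With an estimated correlation 0 of 33 passed (3 at unadjusted p under 0.05), and by fry for a shared direction 0 passed (6 at unadjusted p under 0.05). Fry for change in either direction gave 18, but it does not compare members with other genes, so a pass is not particular to a list. By an exact permutation test of array means, p was 0.0286, the smallest possible, for respiratory chain, xenobiotic metabolism and clock. By the same test it was 0.0571 for acute phase proteins, 0.0857 each for interferon-stimulated genes and PPARα targets, 0.143 for cell cycle and 0.2 for extracellular matrix. Adjusted over the 33 lists, the lowest was 0.236. Of the 35 ways to split the 8 arrays into 4 and 4, 10 gave at least 8 lists, so chance is not excluded for the number of lists.

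**Figure D2:**
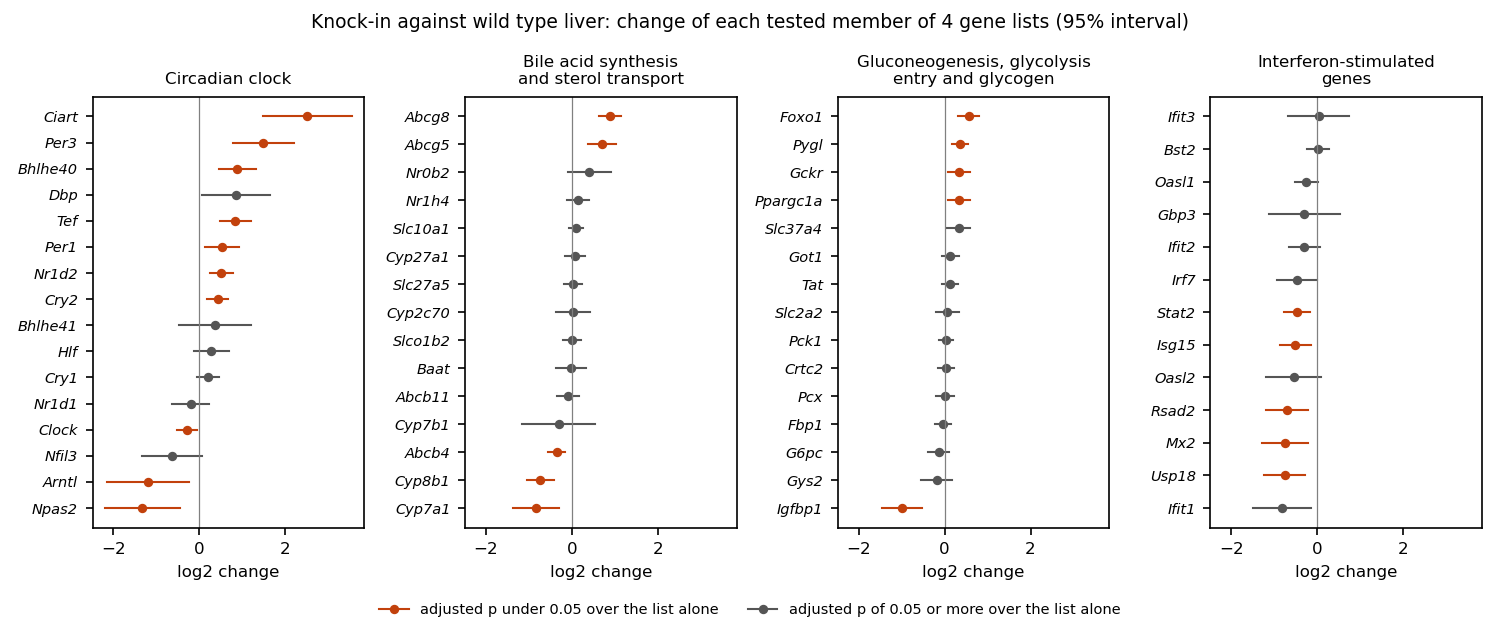
Change of each tested member of 4 lists, as log2 knock-in minus wild type on the horizontal axis (points, limma estimate; lines, 95% interval; 4 arrays per group), in orange where adjusted p over the list alone was under 0.05. Ciart at 2.51 and Npas2 at -1.32 mark the ends of the clock list, Abcg8 and Cyp7a1 those of the bile acid list, and 11 of 13 interferon-stimulated genes lie below 0.

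Of the remaining lists, 0 passed by camera. Lipa, the lysosomal acid lipase, was at -0.33 (SE 0.08) and passed adjusted over the list alone in the lysosome list (adjusted p = 0.868), as did Chac1, at 1.24 (SE 0.25), in the unfolded protein response (0.842) and Cyp2a4, at 2.70 (SE 0.54), among female-biased genes (0.842). Male-biased genes (0.868), NRF2 targets (0.155), pericentral (0.978) and periportal (0.468) genes and the neighbours of Tm6sf2 (0.675) had 0 members past either test; over all genes 0 members of these 8 lists passed. Mean, median and camera direction differed in sign in 7 of the lists that did not pass (lipid droplets, VLDL assembly, unfolded protein response, female-biased, pericentral, sinusoidal endothelium, B and plasma cells).

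By camera, 0 of 9 tested cell type marker lists passed and 0 had an unadjusted p under 0.05. Hepatocyte markers were higher in 10 of 11 members by a small amount, mean 0.04, and their array means did not overlap between groups (exact permutation p = 0.0286, the smallest possible, 0.236 adjusted over the 33 lists; fry for change in either direction, adjusted p = 0.0487). Adjusted p was 0.551 for hepatocytes, 0.618 for stellate cells, 0.842 each for Kupffer cells, sinusoidal endothelium, neutrophils, B and plasma cells and monocyte-derived macrophages with dendritic cells, 0.897 for T and NK cells and 0.978 for cholangiocytes. Jchain, of plasma cells, was at 1.04 (SE 0.25) and alone passed adjusted over its list, and 0 markers passed over all genes. Lyve1, of sinusoidal endothelium, was at 0.73 (SE 0.23). Erythroid, adipocyte, pancreatic acinar and skeletal muscle lists had 2, 2, 2 and 3 tested members and were not tested.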

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

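The tests of the clock arms and of feeding state were chosen after the clock genes had been seen, and the segment and substrain tests after Nnt, Wdfy1, Ide and Nlrp12 had been seen; the substrain gene, Entpd4, had not been looked at, though the test was moved to the probe set shared with Entpd4b, before its values were seen, because no probe set lists Entpd4 alone. The splits of the arrays were planned.

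Splits of the 8 arrays show how far chance goes. The 9 genes past the threshold were reached by 1 of the 35 splits, the real one, with 3 as the highest of the others. The 290 genes of the 1.5-fold count were also reached by 1 of 35, with 190 as the highest other. For both counts this is the smallest share that 35 splits allow, and both come from the same splits. They argue against chance but do not exclude it. At least 8 lists were reached by 10 of the 35 splits, with 11 as the highest other, so chance is not excluded for the lists.

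For the rise of Nnt and the fall of Ide, a segment around Tm6sf2 carried along with the altered allele would place called genes beside it, but Nnt and Ide lie on other chromosomes in GRCm38.p6, 0 of the 9 called genes lay among the 100 annotated genes on either side, and of the 84 neighbours tested 0 passed by limma (5 at unadjusted p under 0.05, lowest adjusted p 0.226). Irs2 and B930025P03Rik, 2 of the 9, do lie on the chromosome of Tm6sf2, with 926 annotated genes between Irs2 and Tm6sf2, and a segment that long was not tested for them. A different C57BL/6 substrain background in the 2 groups may account for Nnt and Ide: the brightest probe set of Entpd4 and Entpd4b, named in advance without a direction, was at -0.58 (exact permutation p = 0.0286, the smallest possible; unadjusted limma p = 0.000226, a value reached by 0.233% of 22772 probe sets; adjusted p = 0.0954), and all 4 such probe sets were lower, by -0.56 to -1.32. Of other genes listed for substrain differences, Wdfy1 was at 1.22 and Nlrp12 at -0.75 (limma adjusted p = 0.054 and 0.0552). Both had been seen before they were listed, so they do not test the explanation. Among those not seen before, Cyfip2 was at -0.10 (limma adjusted p = 0.925), and Gabra2 and Crb1, at -0.15 and 0.02, were below the dim limit. Whether a substrain difference would change the transcript level of these genes in liver was not established. Their values therefore do not argue against the explanation. The labels call every mouse C57BL/6J and the wild type animals littermates, which, if right, goes against a fixed background difference. The labels were not checked against the values. Whether a background difference also bears on the other called genes, such as Gm3893, was not tested. An effect of the variant itself stays open and was not tested.

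The opposed arms of the clock form the other pattern. A difference in the hour of tissue collection could give it: the activators with Nfil3 had a median change of -0.925 and the outputs and repressors 0.531 (10 of 11 higher, Nr1d1 at -0.20), but hours are not given and an effect of genotype on the clock would look alike, so the explanations cannot be told apart. Wild type replicate 4, at 0.27 in outputs minus activators, lay above knock-in replicate 4, at -0.05. Feeding state at collection could move the clock too. Genes higher in the fasted liver had a median of -0.127 (bootstrap range -0.869 to 0.0149) and genes higher in the fed liver 0.159 (-0.0466 to 0.360). The bootstrap resampled genes, not arrays. Of 12 tested fasting genes, 5 were lower at unadjusted limma p under 0.05 (Irs2, Igfbp1, Fgf21, Pdk4 and Igfbp2) and 2 higher (Lpin1 and Ppargc1a). Of 11 tested fed genes, 2 were higher and 1 lower. Feeding state stays open for the clock and for these genes. With the clock score, which is mostly higher in the knock-in, as a covariate, 1 of the 9 genes still passed, with the SE 1.24 to 1.68 times as large over the 9 genes; changes grew for Irs2 (-0.75 to -0.90) and Il17rb (-0.62 to -0.69) and shrank for the other 7, as for Cyp2g1 (1.55 to 1.25), Nnt (1.05 to 0.87), Hspa1a (-0.81 to -0.69) and Ide (-0.94 to -0.88), which does not settle what part the clock has in them.

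In 11 of 190 groups of 4 arrays, 1 array stood far from the other 3, where about 10 are found by chance. In wild type replicate 1 these were Cep72 (3.36, others 2.48 to 2.61), Irs2 (8.69, others 8.94 to 8.96) and Rsad2 (7.39, others 8.03 to 8.09). In wild type replicate 2 it was Srxn1 (7.07, others 7.59 to 7.61), and in wild type replicate 4 the clock genes Ciart (6.66, others 5.18 to 5.29) and Nr1d2 (9.22, others 8.82 to 8.87). In knock-in replicate 2 these were Cyp8b1 (10.3, others 10.8 to 10.9) and A1bg (4.04, others 2.90 to 3.09), and in knock-in replicate 4 Col5a2 (4.40, others 3.94 to 4.02), Stat2 (8.32, others 7.78 to 7.83) and Gstt3 (8.08, others 8.82 to 8.91). Outside the tested genes, 14 of 8607 probe sets without a single symbol passed the threshold, 2 higher and 12 lower, of which 8 belong to the Gm3893 family (-1.92 to -3.37, some with knock-in levels near the dim limit) and 6 have no listed gene.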

How the results depend on the processing

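The clock score as a covariate was chosen after seeing the data; all other alternatives were planned. The count of 9 genes became 2 with the replicate block, 2 with no filter, 32 with the stricter filter, 73 with the trended and robust prior, 25 with array weights, 24 with the mean of probe sets, 24 with every probe set (5 higher, 19 lower) and 1 with the clock score, and 1 to 12 on leaving out each array (12 without knock-in replicate 4, 8 without wild type replicate 3). Fewer or more tests and fewer arrays enter some of these; otherwise the cause was not tested. All 9 genes were among the calls under the trended prior, array weights and mean of probe sets, and 8 under the stricter filter. Without knock-in replicate 4, only Gm3893, Nnt, Ide and Kcnk5 of the 9 passed. Without wild type replicate 3, only Gm3893, Nnt, Ide and B930025P03Rik did. Cyp2g1, Hspa1a, Il17rb and Irs2 passed in 0 of the 8 leave-one-out fits by limma, Nnt in 5 and Ide in 3. The 290 genes became 176 with the stricter filter, 766 with every probe set and 481 with the clock score, and 272 to 361 on leaving out arrays. Lists past the threshold were 0 with an estimated correlation and 0 by fry, and 6 to 9 otherwise, 7 to 8 on leaving out arrays. Tm6sf2 ranged from -0.16 to 0.064 on leaving out arrays and Apob from -0.0197 to 0.0061, with 0.010 after a further quantile normalization. The clock score turned the cell cycle list to -0.0216; it also took Npas2 to 0.0029 and Arntl to 0.25, which its construction fixes, since both are part of the score. The values do not show that replicate numbers pair the arrays. Correlations of same-numbered arrays were 0.101, -0.105, -0.034 and -0.039, and 1 of 4 wild type arrays correlated best with its own number. So few arrays cannot settle whether the numbers mark pairs. Under the replicate block 1 of the 9 genes passed and the same 8 lists did. Signal near the dim limit restricts Gm3893 in knock-in arrays, and Apob and Pck1 lie near the top of the scale.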

Other observations

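The heat shock list was written after Hspa1a and Hspa1b had been seen, and no set test was run on it.

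Among targets of the heat shock factor, the chaperones that cells make under protein stress, 1 of 13 tested members (15 listed), Hspa1a, passed the threshold. The median change was -0.28, and 6 members had an unadjusted limma p under 0.05. Because the list was written around Hspa1a and Hspa1b, these values do not test whether the group changed. Beside Hspa1a at -0.81 (SE 0.10) and Hspa1b at -1.89 (SE 0.29), Hspb1 was at -0.96 (SE 0.25), Hsp90aa1 at -0.53 (SE 0.12), Hsph1 at -0.45 (SE 0.17) and the co-chaperone Bag3 at -0.41 (SE 0.18). The chaperones Hspa8, Hspd1 and Hspe1 were at -0.14, -0.09 and -0.10. No explanation was tested.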
